A study of Homo sapiens with 2 samples.

How the data were processed

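The series measured messenger RNA in mammospheres of 2 human breast cancer cell lines, MCF-7 and T47D, with 1 library per cell line. Mammospheres are clusters that grow when cells are kept from attaching. Per the labels' protocols, the cells grew on plates with a non-adhesive coating in medium with EGF, insulin and B27, and libraries were made with a SMARTER mRNA kit. FastQC 0.11.9 and MultiQC 1.1 are named in the submitters' processing notes. The aligner, the counting tool, the test, the genome build and the annotation release are not given in the sources used here.

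The data analysed were the authors' deposited table of 1 comparison, with 45259 RefSeq transcripts. Per the file headers, the authors deposited a log2 fold change, a p-value and a q-value for each transcript. No value per library was analysed here, so the depth of each library is unknown, and no error, test or p-value was computed across samples. The table held only transcripts with an absolute log2 fold change of 1.00 or more and a p-value up to 0.04999. It does not name the numerator of the ratio. The labels call MCF-7 the control, which does not settle the direction, so rows are described as positive (higher in the numerator library) or negative (higher in the denominator library), and neither side is assigned to a cell line. The deposited q-value never exceeded the p-value of its row, so it is not a usual adjusted p of that column, and neither column was used to rank genes.

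Comparisons planned before the data were examined needed values per library: log2 ratios on TMM-normalised counts, expression filters and random lists matched on mean expression. They could not be computed, and the planned fallback, a description of the authors' own comparison, was used. The fold changes were examined for a common step. A constant of 0.631 was estimated from the commonest values, and a positive row was called whole where its linear ratio divided by that constant was a whole number within a tolerance of 1e-06. For a negative row, the inverse of the linear ratio multiplied by the constant had to be whole, and the whole number is called the multiple of the row. Whole rows from a multiple of 24 (positive) or 15 (negative) upwards are called floor rows. In such a row the ratio carries the reads of 1 library alone, as arises where the other library has 0 or 1 read. The fold change of a floor row is set by the value put in place of few or no reads, so it is not a measured ratio. Against a floor of 3 counts it would be smaller by 1.58 on the log2 scale. On 3 simulated tables built with such a floor, at least 99.96% of positive floor rows were recovered. At least 99.8% of positive rows called floor rows were such rows, but the simulated setting largely fixed that share. In it the other library had almost no reads for most transcripts and levels scattered around a like one for the rest. Low counts above 1 were thus rare. A row with a few reads in the other library can also have a whole multiple, so the share among the deposited floor rows is unknown. Negative floor rows were not checked by simulation.

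Symbols and Ensembl identifiers are those of the authors' deposited table. RefSeq annotation of assembly GRCh38.p14 was used only for biotypes and the number of transcripts per gene, and 43545 transcripts (96.2%) matched it by versioned identifier. GENCODE release 29 gave exon counts. No coordinates are printed, because the build behind the table is not stated. A gene's sign was positive only, negative only or both, over its listed transcripts. Reads of near-identical copies and of transcript variants of 1 gene may have been split by the authors' counting, so values of single transcripts are uncertain where a gene has several.

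The 43 gene lists were fixed before the data were examined. A list's median was taken over the median log2 fold change of each listed gene, and set as a percentile among 10000 random lists of the same size. Because expression levels were not available, random genes were matched on the number of listed transcripts, a choice made after the table was seen. On simulated data, 6% of 200 unchanged lists of 20 genes lay outside the central 95% of random lists, and 100% of lists lowered by 4 on the log2 scale fell below it. Percentiles describe these 2 libraries and are not tests of the cell lines.

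The rule for named genes, fixed beforehand, took (a) 18 fixed genes, (b) the 10 highest and 10 lowest protein-coding genes and (c) up to 2 highest and 2 lowest members of each list. XIST and Y-linked genes were left out. After the table was seen the rule had to be adapted: a gene's value became that of its listed transcript with the largest absolute log2 fold change, part (b) was restricted to genes with rows of 1 sign, and the minimum expression could not be applied. After the alternatives had been seen, part (c) was also restricted to genes with rows of 1 sign, and named genes with rows of both signs were left out of the comparison of alternatives. Neither change was kept, because together they removed from view all 59 reversals of a gene value under an alternative, which concern 45 genes. The rule named 165 genes, of which those needed to describe each list are printed.

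Settings chosen before the data were examined that could be run were a p of 0.01, a 4-fold threshold and protein-coding genes only. Alternatives added after seeing the data were curated transcripts only, coding genes with a single RefSeq transcript, floor rows left out, those single-transcript genes with floor rows left out, and the median over a gene's transcripts. Shares carry Wilson intervals at 95%, which cover counting error only. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.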

Results

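Mammospheres of MCF-7 and T47D, both estrogen receptor-positive lines derived from breast carcinoma, were compared by mRNA sequencing to find genes that differ between them. Each line had 1 library, so there was no replicate error, and every value below compares 2 libraries and not 2 cell lines in general. The depth per library is unknown. Fold changes are those of the authors' deposited table, which does not name the library in the numerator. A gene that is not listed missed the table's thresholds, which does not show that it was equal or absent.

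The authors' deposited table listed 45259 transcripts under 15321 gene symbols, and most of them were positive. It held 37067 positive rows (81.9%) against 8192 negative rows. The median log2 fold change was 5.64 among positive rows and -5.05 among negative rows, and the range ran from -14.83 to 17.21. By gene, 9342 symbols had positive rows only, 1465 had negative rows only and 4514 had transcripts of both signs. Floor rows, whose form arises where 1 library has 0 or 1 read, made up 89.3% of positive rows and 45.5% of negative rows. With floor rows left out, 3949 positive and 4463 negative rows remained, so that the positive share fell to 46.9%. Among protein-coding genes with a single RefSeq transcript, the share was 81.9% (1409 positive and 311 negative rows, Wilson interval 80.0% to 83.7%), and 71.8% with floor rows left out (621 and 244 rows, 68.7% to 74.7%).

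**Figure D1:**
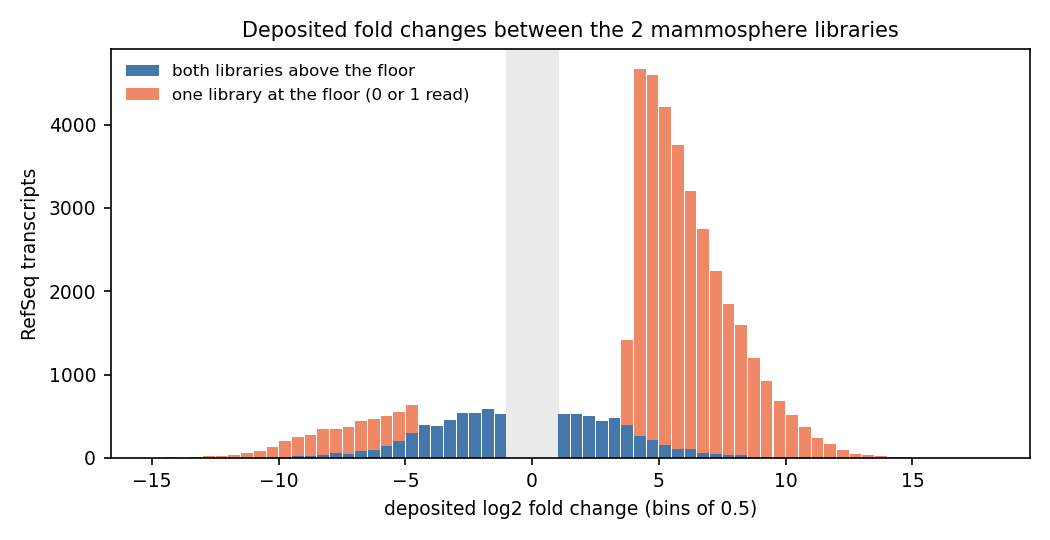
Number of RefSeq transcripts (y axis) by deposited log2 fold change (x axis, bins of 0.5), stacked by whether 1 library was at the floor. The grey band spans the values the table leaves out. Of the positive rows 89.3% were floor rows, against 45.5% of the negative rows.

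NDRG1 (ENSG00000104419), a hypoxia-responsive gene, stood at 17.04 in the authors' deposited table, with 8 positive and 0 negative transcripts. The authors' deposited table gave 15.75 for IGFBP3, which binds insulin-like growth factors, 15.16 for the hypoxia-inducible factor EPAS1 and 14.46 for the angiogenic factor VEGFA. Values of 14.98 for the secreted glycoprotein STC2, 14.51 for the steroid-metabolising enzyme AKR1C1, 14.51 for the stress-induced cytokine GDF15 and 15.10 for the nuclear receptor coactivator NCOA3 stood beside them in the authors' deposited table. The ribosomal protein genes RPL13A, at 15.60, and RPL32, at 14.60, completed the 10 highest genes of the authors' deposited table with rows of 1 sign. All 10 values came from floor rows, so they follow abundance in the numerator library alone. NCOA3 stood at 14.60 and RPL32 at 1.34 with floor rows left out, and the other 8 had no such row.

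The lowest value among genes with rows of 1 sign was that of MSN (ENSG00000147065), which links actin to the membrane, at -14.62 in the authors' deposited table, and GSTP1, a glutathione transferase, stood at -14.34. The authors' deposited table listed the chemokine CXCL3 at -14.32, the granulocyte growth factor CSF3 at -12.93, the matrix protease MMP3 at -13.12 and the smooth muscle actin ACTG2 at -13.13. HLA-G at -13.68 and MAGED1 at -12.79 were also among the 10 lowest in the authors' deposited table. The remaining entries of the authors' deposited table, RPL10L at -14.61 and PPIAP40 at -13.12, are near-identical copies of other genes, and their values are uncertain where reads could be shared. These 10 were floor rows as well, so they follow abundance in the denominator library alone. The values of MSN, HLA-G and PPIAP40 came from predicted transcripts, and none of these genes had a curated transcript listed.

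Of the 18 genes fixed beforehand, 15 were listed, 9 of them with positive rows only, 2 with negative rows only and 4 with both. The authors' deposited table gave 14.01 for the adhesion protein CDH1, 12.45 for CD24, 10.73 for the luminal transcription factor GATA3, 8.05 for AR, 5.84 for FOXA1 and 5.42 for ESR1. GATA3 stood at 3.64 and AR at 4.74 with floor rows left out, and ESR1, whose 5.42 came from a predicted transcript, at 4.04 with curated transcripts only. SOX2 at 7.33, CASP3 at 7.77 and ABCG2 at 5.86 were listed as positive too in the authors' deposited table. VIM, the mesenchymal intermediate filament vimentin, was negative at -12.79, and ALDH1A1, a stem cell-associated dehydrogenase, at -4.66 in the authors' deposited table. Among these genes of 1 sign, all but FOXA1 and VIM took their deposited value from a floor row. Such a value follows abundance in 1 library alone. The genes with both signs in the authors' deposited table were CD44, from -3.13 to 11.43, ERBB2, from -8.23 to 8.61, ALDH1A3, from -5.36 to 6.16, and TP53, from -9.64 to 7.77. Positive and negative rows numbered 17 and 1 for CD44, 14 and 2 for ERBB2, 1 and 1 for ALDH1A3, and 5 and 2 for TP53. ERBB2 stood at -1.37 and CD44 at -3.13 with floor rows left out. PGR, CDKN2A and CCND1 were not listed.

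Of the 43 gene lists, 41 had a listed member and 40 of these had a positive median. The medians of 9 lists lay above the central 95% of random lists and those of 6 below it. About 2.05 would lie outside if genes were drawn independently. Lists share members and their genes may vary together, so that number does not test for an excess. Random lists were not matched on abundance, and 89.3% of positive rows were floor rows, which follow abundance in the numerator library alone. A list's percentile may therefore restate how abundant its genes were there, which was not told apart from a difference between the libraries. The list medians were mostly smaller or of the other sign with floor rows left out, and that value stands beside each list that keeps one. Leaving floor rows out removes 89.3% of positive but 45.5% of negative rows, so a shift to smaller or negative medians arises largely by construction. No random lists were drawn without floor rows, so these medians have no percentile. How many genes of a list kept a row is not given, and some of these medians rest on few genes. The largest absolute value of each gene named with its list below came from a floor row. Exceptions were VIM, RPS8, IER3, EGR3, MYBL1, PLK3 and IFITM2.

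Epithelial junction genes had the highest median of the 41 lists. Of 24 epithelial junction genes, 20 had positive rows only, 0 negative rows only and 4 both, and the median of 7.83 was at percentile 100, but it was 1.84 with floor rows left out. The desmosomal protein DSP stood at 13.81 in the authors' deposited table, and at 11.03 with floor rows left out. The tight junction gene TJP1 ranged from -12.31 to 8.76 there, with -2.41 once floor rows were left out. Among 22 listed genes of luminal identity, 20 were positive only and 2 had both signs, with a median of 6.37 at percentile 99.9, and 4.19 with floor rows left out. KRT18, a luminal keratin, stood at 13.75 in the authors' deposited table.

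Hypoxia and glycolysis lists also lay above the central 95% of random lists. Of 23 listed hypoxia genes, 15 were positive only and 8 had both signs (median 7.49, percentile 100), but with floor rows left out the list's median was -2.27. That median leaves out NDRG1 and VEGFA, which had positive rows only and kept no row. The oxidoreductase ERO1A ranged from -8.86 to 15.79 in the authors' deposited table, with 12 positive rows and 1 negative row. Glycolysis genes were positive only in 9 of 17 and of both signs in 8, with a median of 6.31 at percentile 99.5, and 1.53 with floor rows left out. The authors' deposited table held its highest value, 17.21, for a transcript of the pyruvate kinase PKM, while another PKM transcript stood at -5.67. The lactate dehydrogenase LDHA ranged from -4.21 to 16.17 in the authors' deposited table. Positive and negative rows numbered 14 and 1 for PKM and 5 and 1 for LDHA. The values were 5.49 for LDHA, -5.67 for PKM and -8.86 for ERO1A with floor rows left out.

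Lipid, stress and ribosomal lists were also high. Cholesterol synthesis and uptake genes were positive only in 18 of 24 and of both signs in 6 (median 7.005, percentile 100, and 1.83 with floor rows left out), with INSIG1 at 13.73 and the LDL receptor LDLR at 13.18 in the authors' deposited table. Fatty acid genes were positive only in 12 of 19, negative only in 3 and of both signs in 4 (median 6.08, percentile 98.8, and 2.19 with floor rows left out). The lipogenic regulator SREBF1 stood at 11.49 and the acyl-CoA synthetase ACSL4 at -11.08 in the authors' deposited table, against 2.19 and -4.28 with floor rows left out. ACSL4 stood at -9.09 with curated transcripts only. Heat shock and oxidative stress genes were positive only in 13 of 23, negative only in 1 and of both signs in 9 (median 7.39, percentile 100, and 2.25 with floor rows left out), with the thioredoxin reductase TXNRD1 at up to 14.60 and GSTP1 at the negative end in the authors' deposited table. TXNRD1 stood at 10.40 with floor rows left out. Cytosolic ribosomal protein genes were positive only in 14 of 21, negative only in 1 and of both signs in 6 (median 6.55, percentile 99.97, and 1.03 with floor rows left out). RPS3 stood at 13.45 and RPS8 at -1.07 in the authors' deposited table. Apoptosis genes were positive only in 13 of 26 and of both signs in 13 (median 5.98, percentile 99.1), and their median was -2.41 with floor rows left out. MCL1, an anti-apoptotic protein, ranged from -4.37 to 13.85 in the authors' deposited table, and only its -4.37 was not a floor row.

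Mesenchymal genes lay low. Of 16 listed mesenchymal and EMT genes, 7 were positive only, 5 negative only and 4 of both signs (median 3.22, percentile 1.32, and -2.57 with floor rows left out). The 5 negative-only members compare with 1.90 on average in random lists, of which 2.68% had as many. Besides VIM, the authors' deposited table listed ZEB1, a repressor of epithelial genes, from -10.43 to 3.98, and the matrix enzyme LOX at 13.44. Of 12 fibroblast markers only 4 were listed, 1 positive only, 2 negative only and 1 of both signs (median -7.04, percentile 0.01, but 2.27 with floor rows left out). COL3A1, a fibrillar collagen, stood at -10.57 and LUM, a matrix proteoglycan, at -9.33 in the authors' deposited table. Each had 1 row, a floor row, so the fibroblast value of 2.27 leaves both out. It rests on the few other listed markers, among them FBLN1 at 1.19.

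The other low lists were Hedgehog, G1 regulator, immediate early and housekeeping genes. Hedgehog pathway genes were 1 positive only, 1 negative only and 4 of both signs among 6 listed (median 1.097, percentile 0.92, and -1.67 with floor rows left out), with SMO, the pathway's signal transducer, at -9.96 in the authors' deposited table. Cyclin-dependent kinase inhibitors and G1 regulators were 5, 3 and 3 of 11 (median 2.33, percentile 2.33, and -2.58 with floor rows left out). CDKN1A ranged from -2.67, its value with floor rows left out, to 13.51 and CCND2, cyclin D2, stood at -10.51 in the authors' deposited table. CDKN1A had 9 positive rows and 1 negative row. Immediate early genes were 11, 2 and 4 of 17 (median 3.90, percentile 1.08, and 3.38 with floor rows left out), with IER3 at 11.15 and EGR3 at -2.04 in the authors' deposited table. Housekeeping reference genes were 7, 1 and 6 of 14 (median 3.86, percentile 1.61, and 1.59 with floor rows left out), with RPLP0 at 12.50 and TUBB ranging from -12.36 to 11.91 in the authors' deposited table.

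**Figure D2:**
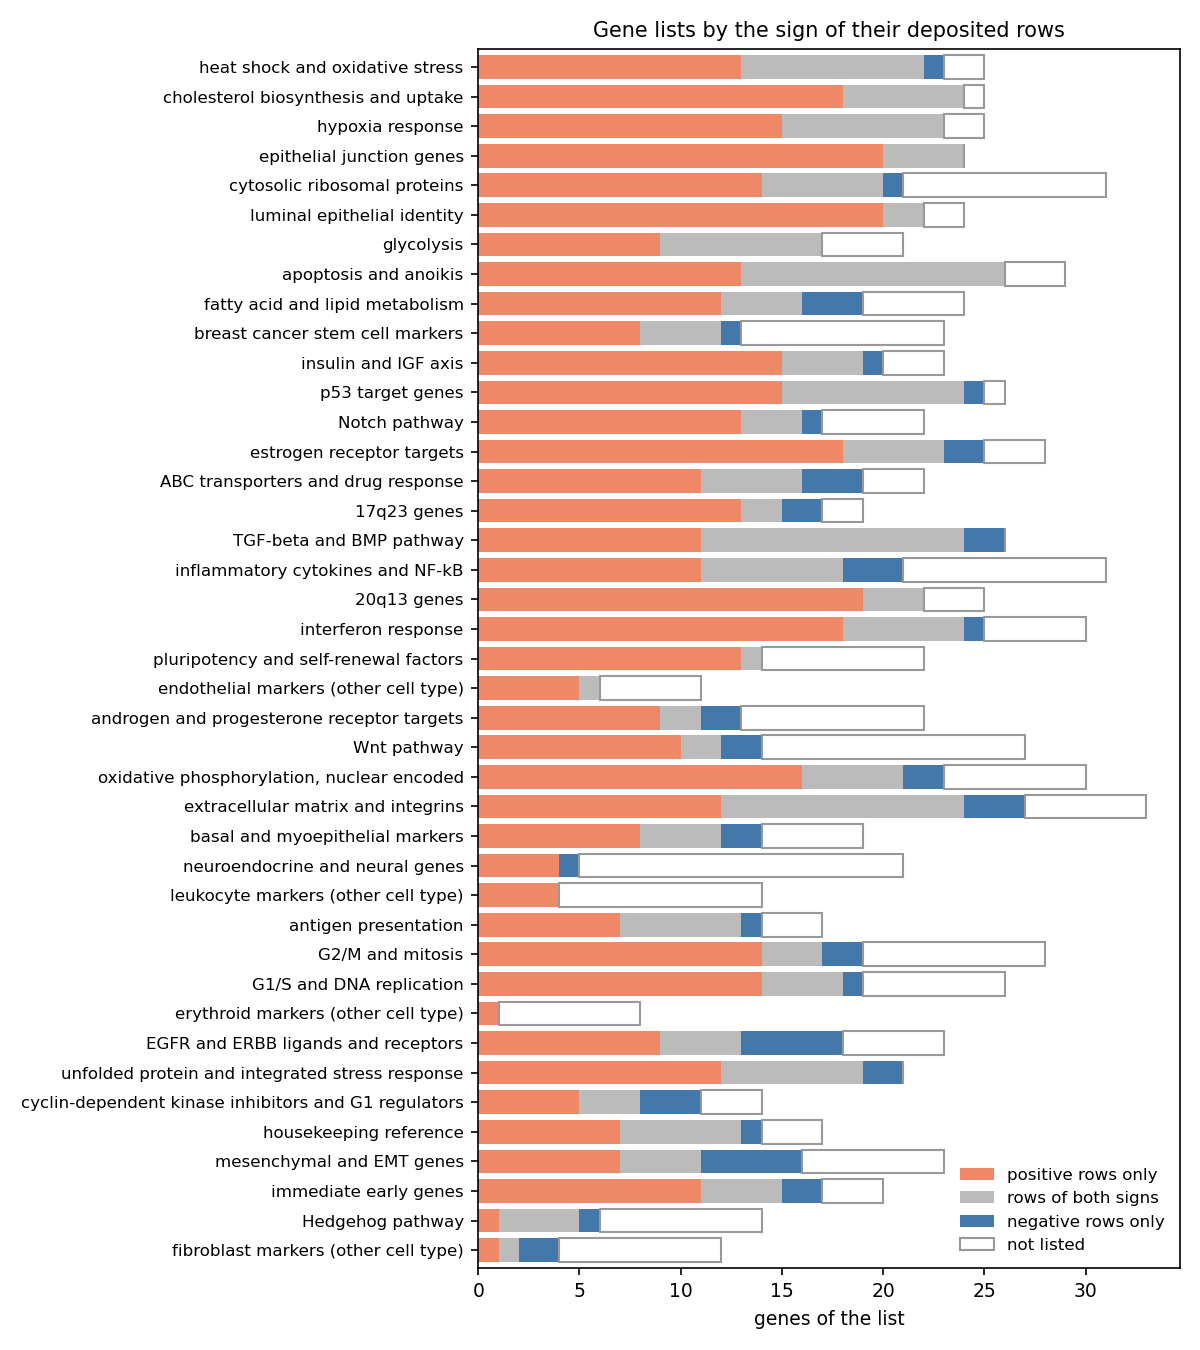
Number of genes (x axis) of each of the 41 lists with a listed member, ordered by the percentile of the list's median. Colours give genes with positive rows only, both signs or negative rows only, and open bars give genes that were not listed. Epithelial junction genes had 20 positive-only and 0 negative-only members, and fibroblast markers had 1 and 2.

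**Figure D3:**
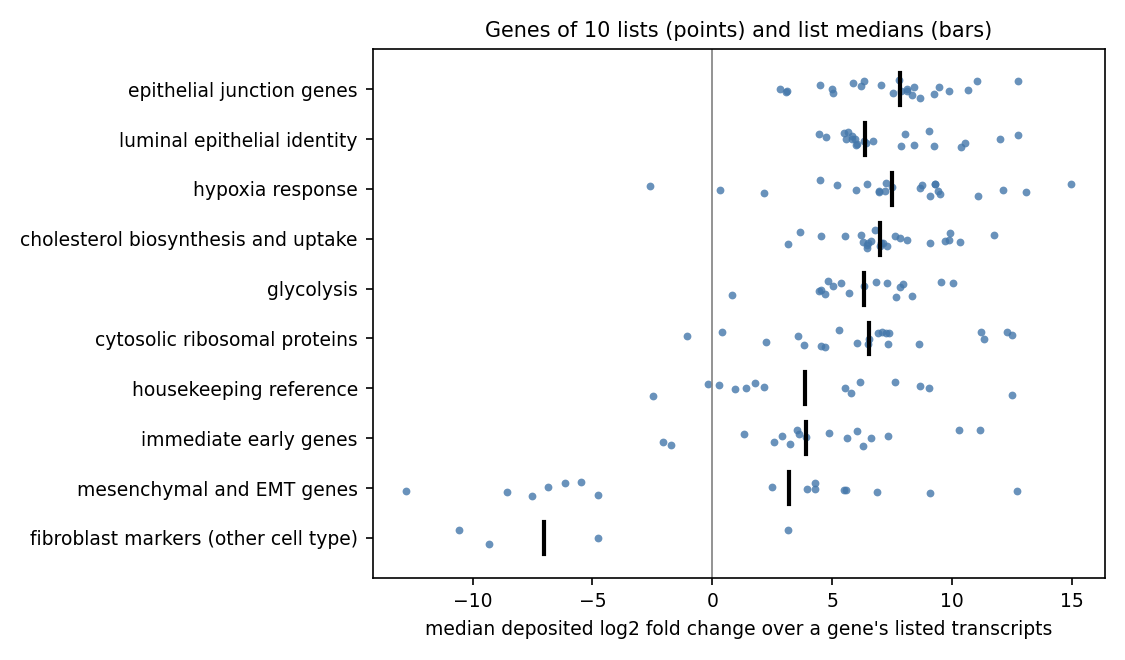
Median deposited log2 fold change of each listed gene (points, x axis) in 10 lists, with the list median as a bar. Points are shifted vertically at random for visibility. List medians ran from -7.04 for fibroblast markers to 7.83 for epithelial junction genes.

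The medians of the remaining hormone and breast lineage lists lay within the random range. In the order positive only, negative only and both signs, estrogen receptor targets were 18, 2 and 5 of 25 (median 5.40, percentile 93.9, and 2.02 with floor rows left out), with the lysosomal protease CTSD at 13.37 and MYBL1 at -3.12 in the authors' deposited table. Androgen and progesterone receptor targets were 9, 2 and 2 of 13 (median 5.19, percentile 79.2, and 3.06 with floor rows left out), with S100P at 13.12 and ZBTB16 at -6.81 in the authors' deposited table. Basal and myoepithelial markers were 8, 2 and 4 of 14 (median 5.24, percentile 74.4, and 3.46 with floor rows left out), and the authors' deposited table set the basal keratins apart, KRT17 at 11.77 and KRT14 at -9.41. Breast cancer stem cell markers were 8, 1 and 4 of 13 (median 6.01, percentile 97.0, and -3.13 with floor rows left out), with the adhesion molecule EPCAM at 12.02 in the authors' deposited table. Pluripotency factors were 13, 0 and 1 of 14 (median 5.38, percentile 87.8, and 2.93 with floor rows left out), with SOX9 at 10.34 in the authors' deposited table.

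Medians of the following signalling lists also lay within that range. Notch pathway genes were 13, 1 and 3 of 17 (median 5.61, percentile 94.8, and 2.90 with floor rows left out), with the receptor NOTCH3 at 12.65 and NOTCH4 at -7.53 in the authors' deposited table. Wnt pathway genes were 10, 2 and 2 of 14 (median 5.22, percentile 79.0, and 2.83 with floor rows left out), with the receptor FZD8 at 9.46 and the ligand WNT5A at -7.48 in the authors' deposited table. TGF-beta and BMP genes were 11, 2 and 13 of 26 (median 5.56, percentile 92.9, and -1.71 with floor rows left out), with TGFB3 ranging from -11.44 to 6.80 in the authors' deposited table. EGFR and ERBB genes were 9, 5 and 4 of 18 (median 4.60, percentile 22.9, and -1.37 with floor rows left out). Its 5 negative-only members compare with 1.59 on average in random lists, of which 1.40% had as many, the smallest such share among the lists. The phosphatase DUSP4 stood at 12.53 and the ligand NRG1 at -10.67 in the authors' deposited table. Insulin and IGF genes were 15, 1 and 4 of 20 (median 5.72, percentile 95.8, and 3.04 with floor rows left out), with the kinase AKT3 at -11.25 in the authors' deposited table. IGF1R stood at 12.31 for a predicted transcript of the authors' deposited table, and at 2.11 both with curated transcripts only and with floor rows left out.

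Medians of the proliferation, damage, energy and drug response lists lay within the range too. G1/S and replication genes were 14, 1 and 4 of 19 (median 4.76, percentile 46.5, and 1.72 with floor rows left out), with MCM7 at 9.93 in the authors' deposited table, at 9.60 with curated transcripts only and at 1.33 with floor rows left out. G2/M and mitosis genes were 14, 2 and 3 of 19 (median 4.65, percentile 51.7, and 2.78 with floor rows left out), with NUSAP1 at 7.25 and KIF23 at -7.23 in the authors' deposited table. The KIF23 value came from a predicted transcript, its only listed row. Targets of p53 were 15, 1 and 9 of 25 (median 5.73, percentile 95.7, and 1.96 with floor rows left out), with PLK3 at -3.07 in the authors' deposited table. Nuclear-encoded oxidative phosphorylation genes were 16, 2 and 5 of 23 (median 5.19, percentile 75.2, and 1.29 with floor rows left out), with COX4I1 at 12.37 and ATP5F1A ranging from -12.07 to 10.44 in the authors' deposited table. Unfolded protein and integrated stress response genes were 12, 2 and 7 of 21 (median 4.20, percentile 2.93, and 0.949 with floor rows left out). TRIB3, a stress-induced pseudokinase, stood at 13.23 and the serine synthesis enzyme PSAT1 at -9.18 in the authors' deposited table. ABC transporters and drug response genes were 11, 3 and 5 of 19 (median 5.58, percentile 93.3, and 1.17 with floor rows left out), with the cytochrome CYP1A1 at 13.32 in the authors' deposited table, and at 1.17 with floor rows left out.

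Immune, matrix and amplified-region lists completed the set. Interferon response genes were 18, 1 and 6 of 25 (median 5.45, percentile 91.1, and -3.56 with floor rows left out), with IFITM3 at 9.93 and IFITM2 at -5.33 in the authors' deposited table. Antigen presentation genes were 7, 1 and 6 of 14 (median 4.84, percentile 56.9, and -3.39 with floor rows left out), with B2M at 13.06 and HLA-A ranging from -9.25 to 12.43 in the authors' deposited table. The value of HLA-A was -7.19 with curated transcripts only and -9.25 with floor rows left out. Inflammatory cytokines and NF-kB genes were 11, 3 and 7 of 21 (median 5.55, percentile 92.5, and -2.06 with floor rows left out), with CXCL8 at 11.28 in the authors' deposited table. Extracellular matrix and integrin genes were 12, 3 and 12 of 27 (median 5.21, percentile 74.5, and -2.31 with floor rows left out), with ITGAV ranging from -13.15 to 11.71 in the authors' deposited table. ITGA5 stood at 13.20 for a predicted transcript of the authors' deposited table, and at 2.26 both with curated transcripts only and with floor rows left out. Genes of 17q23 were 13, 2 and 2 of 17 (median 5.74, percentile 93.0, and 3.24 with floor rows left out), with RPS6KB1 at 11.34 in the authors' deposited table, and at 7.13 with floor rows left out. Genes of 20q13 were 19, 0 and 3 of 22 (median 5.62, percentile 91.4, and 3.93 with floor rows left out), with NCOA3 at 15.10 and ZNF217 at 13.63 in the authors' deposited table, and at 14.60 and 5.12 with floor rows left out.

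Markers of other cell types were thinly listed. Endothelial markers were 5, 0 and 1 of 6 (median 5.50, percentile 81.2, and -3.79, the value of EGFL7 alone, with floor rows left out), leukocyte markers 4, 0 and 0 of 4 (median 5.07, percentile 63.9) and erythroid markers 1, 0 and 0 of 1 (median 4.47, percentile 45.7). Neuroendocrine and neural genes were 4, 1 and 0 of 5 (median 5.21, percentile 69.8). None of the 13 mitochondrially encoded genes and none of the 22 cancer-testis antigens were listed.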

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

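The settings that use curated transcripts, single-transcript genes, floor rows and medians over transcripts were chosen after seeing the data. No paired analysis was possible because each cell line had 1 library. Other settings chosen before the data were examined, on normalisation, expression filters, prior counts, counting intervals, thinning and replicates, were not run, since they need values per library. A p of 0.01 kept every count of transcripts and genes within 1.5 times its value. The positive share was 83.6% at 4-fold or more, 81.2% for protein-coding genes and 83.7% for curated transcripts. Curated transcripts left 22779 positive and 4430 negative rows and 2422 genes of both signs, as fewer transcripts enter. Coding genes with a single transcript gave 1409 positive and 311 negative rows, again by construction. With floor rows left out, 3949 positive and 4463 negative rows remained, a positive share of 46.9%. Leaving floor rows out of the single-transcript coding genes gave 621 positive and 244 negative rows, a positive share of 71.8%. Removing floor rows also removes large changes, so neither share shows where the excess comes from. The cause of the difference between these shares was not tested. By gene, 2528 symbols were then positive only, 2987 negative only and 775 of both signs.

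With floor rows left out, 38 lists kept a median, of which 14 reversed, and the cause was not tested beyond the removal of rows. That removal took 89.3% of positive but 45.5% of negative rows, so a shift towards negative medians arises largely by construction. Of the reversed medians 4 lay within the list's own bootstrap range (Hedgehog, mesenchymal and EMT, G1 regulators and fibroblast markers) and 10 outside it. Of the medians that kept their sign, 5 lay within it and 19 outside. The bootstrap ranges were drawn over all listed genes, while a list may keep fewer genes without floor rows. The reversed endothelial median was the value of EGFL7 alone. Those of breast cancer stem cell markers, Hedgehog genes and G1 regulators equalled the values of CD44, CDON and CDK6. That of fibroblast markers was taken without COL3A1 and LUM, which kept no row. The reversed medians were breast cancer stem cell markers -3.13, mesenchymal and EMT genes -2.57, Hedgehog pathway -1.67, TGF-beta and BMP pathway -1.71, EGFR and ERBB ligands and receptors -1.37, cyclin-dependent kinase inhibitors and G1 regulators -2.58, apoptosis and anoikis -2.41, hypoxia response -2.27, interferon response -3.56, antigen presentation -3.39, inflammatory cytokines and NF-kB -2.06, extracellular matrix and integrins -2.31, fibroblast markers (other cell type) 2.27, endothelial markers (other cell type) -3.79. At 4-fold or more, and with curated transcripts, none of the 41 list medians reversed or left its bootstrap range.

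Over 3 alternatives there were 59 reversals of a named gene's value, in 45 genes, all with transcripts of both signs, where the choice of transcript sets the sign. With the median over transcripts, 96 of 162 values moved without reversing and 45 stayed the same. NDRG1 went from 17.04 to 9.43, IGFBP3 from 15.75 to 9.59 and VEGFA from 14.46 to 8.74. Leaving floor rows out moved 25 values without reversing them. With floor rows left out, the 21 reversed log2 fold changes were ERBB2 -1.37, CD44 -3.13, NQO1 -2.34, SLBP -2.39, CDON -1.67, NOTCH2 1.41, TSC22D3 4.12, HLA-A -9.25, MCL1 -4.37, BBC3 -1.40, CDKN1A -2.67, CDK6 -2.58, RPL18 -5.12, EGFL7 -3.79, LAMA5 -1.58, PKM -5.67, PFKM 3.87, YWHAZ -7.20, ERO1A -8.86, ATF3 -5.79, EZH2 3.39. With the median over transcripts, 21 reversed to TP53 4.47, MCM3 5.44, CCNE2 4.51, TSC22D3 4.98, HLA-A -6.29, HLA-F 4.29, BCL2L1 4.90, BAX 4.86, LAMA3 4.71, CCND3 4.55, TJP1 2.81, ITGAV 8.85, PFKL 6.31, PFKM 4.83, TUBB 5.55, KLF6 6.04, FOXO1 2.30, ATP5F1A 5.19, NDUFS1 4.47, EZH2 3.66, PHGDH 5.42. With curated transcripts only, 17 reversed to TSHZ2 4.14, BMPR1B 4.04, TSC22D3 8.33, HLA-A -7.19, HLA-F 4.62, BCL2L1 6.13, CDK6 -2.58, CCND3 5.94, COL4A5 8.21, PFKL 10.77, AKR1B10 5.95, HMBS 4.86, CSF1 5.27, FOXO1 2.73, RSAD2 5.60, EZH2 7.41, PHGDH 9.47. The authors' deposited table gives no depth, and with 1 library per cell line the precision of values across libraries is unknown. If multiples are numbers of reads, floor rows alone held 1.41e+07 reads of the numerator library and 1.15e+06 of the denominator library. The full depth stays unknown.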

Other observations

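All tests below except those of zinc finger genes and of 1-exon genes were chosen after the result was seen, with bounds set knowing the values. The bound for fibroblast markers was also rewritten after its value was known, because markers that are not listed exclude nothing. The name pattern for ribosomal genes was corrected after it had been found to drop some of them.

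Of 15321 genes in the authors' deposited table, 4514 (29.5%) had transcripts of both signs. The widest spans, picked after their values were seen, were those of APLP2, from -14.83 to 12.43, ST13, from -13.89 to 12.08, and EIF3L, from -13.20 to 11.90. Negative rows made up 5.50% of 2510 lncRNA rows, 18.8% of 40400 protein-coding rows and 20.2% of 515 rows of transcribed pseudogenes, and these differences were not tested.

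Positive rows outnumbered negative rows by 37067 to 8192. Lower depth of the denominator library would leave no abundant transcript at the floor, but 2490 of 33118 positive floor rows had a multiple of 1000 or more, while 207 negative ones did too. The median multiple of positive floor rows was 93, so this argues against depth for the abundant rows only. Depth stays open for the others. Reads shared among transcript variants would balance in coding genes with a single transcript, yet these were 81.9% positive, with a lower Wilson bound of 80.0%. With floor rows left out the positive share was 46.9% over all rows but 71.8% in those single-transcript genes, and leaving floor rows out also removes large changes. A single scaling factor could turn the sign of the 2490 and 207 rows only if it were of the size of their multiples. Those counts argue against the authors' scaling for these rows, and for the other rows it stays untested. A difference between the cell lines stays open and untested, since no library totals were analysed and the numerator is not named.

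Some transcripts that human cells are known to use widely were at the floor in the denominator library. Among 38 listed genes with ribosomal or respiratory chain names and a single RefSeq transcript, 22 were at this floor, 13 of them with a multiple of 1000 or more, such as RPL39 and COX7C. The other 16 were not, of which 5, such as RPS13 at 10.06, stood at 4.69 or more and 5, such as RPS8, were negative. The names also took in the assembly factors NDUFAF4, COX10 and COX19 and the readthrough gene ATP5MF-PTCD1, all but COX10 at the floor. For comparison, 788 of all 1720 listed coding genes with a single RefSeq transcript were at the same floor. Genes with such names that missed the table's thresholds were not counted. Reads from another organism are a candidate explanation, under which zinc finger genes, many of them not shared between mammals, would be negative less than 0.5 times as often as other genes. Their ratio was 0.826, with a bootstrap range from 0.678 to 0.976, which reached neither that bound nor 1, so this cannot be told apart from other losses of transcripts. Another human cell type, reads placed on other copies of these genes by the authors' counting, and a biological difference between the cell lines were not tested.

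The 10 lowest genes included the known intronless copies RPL10L and PPIAP40, and 5 of 16 listed mesenchymal and EMT genes, VIM among them, had negative rows only. Reads of parent genes assigned to near-identical copies could raise 1-exon genes: these were negative in 22.7% of 181 genes (Wilson interval 17.2% to 29.3%) against 17.7% of 1392 genes with several exons, a ratio of 1.28. That is short of the predicted 1.5, although it was 1.504 against genes of like absolute fold change, and the intervals overlap. Mesenchymal cells in the denominator library are a hypothesis for which 3 of 12 fibroblast markers had a negative row, 1 was positive only and 8 were not listed, with COL3A1 at -10.57 and LUM at -9.33 in the authors' deposited table. Neither explanation can be told apart from a difference between the lines, because the table is truncated and the copies are few. Luminal identity genes went the other way, 20 of 22 listed being positive only and 0 negative only. CDH1 at 14.01, KRT18 at 13.75, EPCAM at 12.02 and ESR1 at 5.42 came from floor rows. Both lines are estrogen receptor-positive, so ESR1 at the denominator's floor would be an unexpected difference between them. Other ESR1 transcripts may have missed the thresholds, and this was not tested.

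At a multiple of 29, 426 of 440 positive rows had a q-value under 1e-07 and 14 had one over 5e-07, with 0 between. At a multiple of 24, the 506 positive rows shared 1 fold change but had 506 different p-values, from 1.24e-11 to 0.04999, in the authors' deposited table. The p-value was 0 in 28558 rows and lay above the q-value in 16701.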
